A study of Homo sapiens with 8 samples.

How the data were processed

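The series holds 8 one-colour Affymetrix HG-U133A 2.0 arrays of biotin-labelled RNA from Caco-2 cells, 2 for each of control day 5, quercetin day 5, control day 10 and quercetin day 10. Per the labels' protocols, cells of passage 37 were seeded in triplicate at about 40000 cells per square centimetre in medium with 10% serum and reached confluency after 2 days, which was taken as day 0 and the start of exposure. They were exposed for 9 days in all, to quercetin with 1 mM ascorbate or to 1 mM ascorbate alone. Groups were read from the sample titles, which give treatment, day and sample number.

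The deposited table holds intensity values, that is linear probe set signals scaled by the authors to a common trimmed mean on each array. This was checked on the values: none of the 22277 signals per array was 0 or negative, they reached 11103, and the 2% trimmed mean was 200.1 on all 8 arrays. The summarisation software and the target value are not stated. Per the labels' description, the authors left out 7285 probe sets called absent (detection P of 0.065 or more) on all 8 arrays, but the deposited table still holds all probe sets and no detection calls.

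The signals were taken as log2(signal + 1) with no further normalization between arrays. The 7285 probe sets of lowest mean, the number the authors called absent, and 62 control probe sets were left out, which left 14934. The lowest mean log2 value tested was 3.53, a signal of about 10.5. The annotation gave 1 gene symbol to 19070 probe sets, several to 1043 and none to 2164. A gene was represented by its probe set of highest mean among those with 1 symbol, which gave 8582 genes. Genomic positions were not needed for any value.

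A linear model with 4 group means was fitted per probe set with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (4 residual and 8.25 prior degrees of freedom). The 3 main comparisons were quercetin minus control on day 5, the same on day 10, and day 10 minus day 5 in control cells. The other 3 were day 10 minus day 5 in quercetin-treated cells, the difference between the quercetin effects of the days, and their average. Tests were two-sided, with p adjusted by Benjamini-Hochberg over all probe sets of a comparison and a threshold of 0.05. Fold values are 2 raised to the absolute log2 difference. Values given as mean ± SD are signals, and SE belongs to a log2 difference.

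The samples, comparisons, 29 gene lists, rule for named genes and alternatives listed below were chosen before the data were examined. Lists were tested on 1 probe set per gene with limma's camera at a preset correlation of 0.01 between genes, with p adjusted over the 29 lists, and again with an estimated correlation and with fry. At the preset correlation 20 lists passed on day 5, 14 on day 10 and 12 in the control course, with an estimated correlation 2, 0 and 3, and with fry, which asks only whether a list's genes move on balance in a given direction, 20, 19 and 18. For some lists the estimate lay below the preset 0.01, such as -0.013 for MAPK feedback and immediate early genes and -0.025 for NRF2 targets. For such lists the larger p with an estimated correlation does not reflect a stronger correlation between genes. The rule for named genes took, for each main comparison, up to 10 genes each way with the largest log2 difference among those that passed and whose groups did not overlap, and up to 4 members of each described list with the smallest p, or other members that passed. It took up to 5 genes each way in the other comparisons. Genes outside the rule are said to be so. Which lists to describe was decided after their results were seen.

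Correlations between comparisons were computed across genes, beside 100 simulations of unchanged groups that share the same arrays and from disjoint arrays. They carry no p, since genes are not replicates. The sample numbers were checked as pairs: deviations of same-numbered arrays from their group means correlated at -0.031 to 0.047 over 6 pairs of groups, under the preset limit of 0.1, so arrays were treated as unpaired.

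The fit was tested on simulated data with 200 changed probe sets in 14934, in 10 simulations for each main comparison. Probe sets varied independently there, and fewer changed than were called in the real comparisons, so the shares below hold for that setting only. Of true log2 changes of 0.5, 1 and 2, the day 5 comparison recovered 9.12, 35.9 and 69.1%, and 3.79% of its calls were false. The day 10 comparison recovered 8.16, 36.8 and 68.5% with 4.58% false, and the control course 9.06, 37.4 and 70.1% with 4.64% false. Each list test found a list shifted by 0.5 in 10 of 10 simulations and called 0 of 270 unchanged lists. Genes were simulated as independent, whereas the estimated correlation was 0.159 in the real mitosis list. The simulations therefore do not show how often correlated lists are called falsely.

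The alternatives were quantile normalization, centring each array on its median, no filter on low values, a filter that left out the lower 50% of probe sets, a log offset of 32, no trend in the variance prior, the sample number as a block, a change of at least 2-fold, the mean of all probe sets of a gene, only the 4 arrays compared, and leaving out each array in turn. Where an array was left out, the lone array of its group was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9, and tables read with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.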

Results

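Messenger RNA was measured in Caco-2 cells, a human colon cancer cell line that takes on features of small-intestinal enterocytes after it reaches confluency. Cells of passage 37 on permeable membrane inserts received quercetin, a plant flavonol, stabilised with 1 mM ascorbate, or 1 mM ascorbate alone as the control. RNA was taken 5 and 10 days after confluency, which gave 4 groups of 2 arrays: control day 5, quercetin day 5, control day 10 and quercetin day 10. Each of the 8 arrays measured 22277 probe sets. The labels give no dose of quercetin. The median signal per array ranged from 38.0 to 45.2, and the trimmed mean was 200.1 on every array. Across probe sets, which are not independent replicates, the log2 signals of the 2 arrays of a group correlated with r between 0.959 and 0.969. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.41 to 1.78 for actin and 0.868 to 0.951 for GAPDH. The number of arrays limits the precision of every value. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

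The main axis of variation separated both the days and the treatments. The first principal component of the probe sets tested held 47.2% of the variance. On it, the quercetin arrays lay at -64.5 and -64.3 on day 5 and at 18.1 and 20.1 on day 10, and the control arrays at -10.2 and -12.2 on day 5 and at 60.5 and 52.5 on day 10. On the second component, 13.2% of the variance, the arrays of control day 10 lay at 11.45 and -13.4, the widest gap within a group, and their r of 0.959 was the lowest of the 4 groups. Quercetin-treated cells lay on the day 5 side of the control cells of the same day on the first component.

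The study's stated design compares quercetin with control cells on each day. On day 5, some brush border and lipid transport genes were lower in quercetin-treated cells, and CEACAM6 and the cytochrome P450 gene CYP1A1 were higher. SI (206664_at), the brush border enzyme sucrase-isomaltase, fell 34.4-fold, from a signal of 921 ± 105 to 25.8 ± 2.62 (SD, n = 2 arrays per group), a log2 difference of -5.11 ± 0.128 (SE) with an adjusted p of 3.6e-10. With a log offset of 32 its log2 difference was -4.04. CYP1A1 (205749_at), an enzyme of polycyclic hydrocarbon metabolism induced through the aryl hydrocarbon receptor, rose 14.1-fold, from 106 ± 11 to 1510 ± 135, a log2 difference of 3.82 ± 0.14 with an adjusted p of 1.69e-08. CEACAM6 (211657_at), a carcinoembryonic antigen cell adhesion molecule, rose 4.98-fold, from 573 ± 62.2 to 2851 ± 113. With limma, 2170 of the 14934 probe sets tested differed at an adjusted p under 0.05, 866 higher and 1304 lower in quercetin-treated cells. By gene, 1378 of 8582 differed, 532 higher and 846 lower.

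Brush border and enterocyte markers formed the group with the largest mean fall on day 5 among the lists described. Of its 33 measured members, 20 fell, 4 rose and 9 did not pass, or 22 and 4 adjusted over the list alone, with a mean log2 difference of -0.94 (list adjusted p = 1.16e-07, but adjusted p = 0.088 with an estimated correlation). SLC26A3, an intestinal chloride and bicarbonate exchanger, fell by 2.85, and MEP1A, a brush border metalloprotease subunit, fell by 2.64 on the log2 scale. The members that rose included CEACAM6 and CEACAM5 (log2 differences 2.32 and 3.54), which are cell surface glycoproteins. The keratin KRT20 and CEACAM1 rose as well, by 1.229 and 1.199. Of the 11 measured markers of goblet, Paneth, enteroendocrine and stem-like cells, 3 fell, none rose and 8 did not pass, also 3 adjusted over the list alone (mean -0.30, list adjusted p = 0.0479, but adjusted p = 0.181 with an estimated correlation). Of 19 genes of lipoproteins and lipid transport, 10 fell, none rose and 9 did not pass, or 12 fell adjusted over the list alone (mean -0.86, list adjusted p = 4.18e-11, and adjusted p = 0.0444 with an estimated correlation). APOB, the structural protein of chylomicrons, fell 3.53-fold from 3214 ± 210 to 909 ± 15.9, and MTTP, which loads lipid onto it, fell by 2.76 on the log2 scale.

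Among inflammatory and acute phase genes and among drug-metabolising enzymes, more members fell than rose on day 5. Among 35 inflammatory and acute phase genes, 13 fell, 4 rose and 18 did not pass, or 15 and 4 adjusted over the list alone (mean -0.43, list adjusted p = 3.36e-04, but adjusted p = 0.0726 with an estimated correlation). The fibrinogen chains FGB, FGA and FGG changed by -2.37, -2.22 and -1.38 on the log2 scale, and alpha-fetoprotein, AFP, by -1.64, whereas PTGS2, the inducible cyclooxygenase, rose by 2.92. Among 37 genes of phase I and II metabolism and drug transport, 18 fell, 1 rose and 18 did not pass, or 21 and 3 adjusted over the list alone (mean -0.77, list adjusted p = 4.93e-08, but adjusted p = 0.0726 with an estimated correlation). The sulfotransferase SULT1C2 fell by 1.82, the epoxide hydrolase EPHX2 by 1.45 and the glutathione transferase GSTA1 fell by 1.20 on the log2 scale.

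Some targets of the antioxidant regulator NRF2 and of the aryl hydrocarbon receptor rose on day 5. Of 30 NRF2 targets, 15 rose, 1 fell and 14 did not pass, or 16 and 2 adjusted over the list alone (mean 0.48, list adjusted p = 2.19e-07, and adjusted p = 0.0495 with an estimated correlation). AKR1C1, an aldo-keto reductase, rose 2.26-fold from 1748 ± 176 to 3939 ± 5.34, TXNRD1, a thioredoxin reductase, rose 2.25-fold, and NQO1, a quinone reductase, rose 1.94-fold. Of 14 aryl hydrocarbon receptor targets, 7 rose, none fell and 7 did not pass, or 8 rose adjusted over the list alone (mean 0.83, list adjusted p = 1.06e-05, but adjusted p = 0.088 with an estimated correlation). They included CYP1A1 and the efflux transporter ABCG2 (log2 difference 0.88), and NQO1 and TXNRD1 belong to both lists. Probe sets for near-identical relatives, such as the AKR1C and CEACAM genes, can bind each other's transcripts, which was not tested.

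Some members of the stress, growth-signal and cell division lists rose on day 5 as well. Of 21 heat shock proteins, 11 rose, 1 fell and 9 did not pass, or 14 and 1 adjusted over the list alone (mean 0.49, list adjusted p = 2.19e-07, but adjusted p = 0.088 with an estimated correlation), with FKBP4, HSPH1 and HSPB1 higher by 1.65, 1.13 and 1.24 on the log2 scale. Of 24 MAPK feedback and immediate early genes, 9 rose, 1 fell and 14 did not pass, or 15 and 1 adjusted over the list alone (mean 0.62, list adjusted p = 5.17e-06, but adjusted p = 0.0558 with an estimated correlation), with IER3 at 1.32, the phosphatase DUSP5 at 1.81 and MYC at 1.28. Of 42 genes of the unfolded protein and amino acid response, 12 rose, 2 fell and 28 did not pass, or 16 and 2 adjusted over the list alone (mean 0.32, list adjusted p = 3.60e-04, but adjusted p = 0.145 with an estimated correlation), with TRIB3 at 0.99 and the glycyl-tRNA synthetase GARS1 at 0.89. Of 47 mitosis genes, 20 rose, 1 fell and 26 did not pass, or 23 and 1 adjusted over the list alone (mean 0.39, list adjusted p = 7.42e-10, but adjusted p = 0.147 with an estimated correlation). MKI67, a marker of dividing cells, rose 1.97-fold from 588 ± 20.1 to 1156 ± 54.8.

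Among genes that passed, the 10 largest rises on day 5 were in MMP7, a matrix metalloprotease, AKAP12, CYP1A1, CEACAM7, CEACAM5, QSOX1, CCDC134, IFITM3, PTGS2 and TRABD, with log2 differences from 4.20 down to 2.83. The 10 largest falls were in SI, the glucose transporter SLC2A2, GPR143, BLNK, the brush border enzyme MGAM, the bile acid synthesis enzyme AKR1D1, SORBS2, GPC5, XPNPEP2 and CEL, from -5.11 to -3.11. In 11 of these 20 genes a compared group had a mean signal below 10.5, the lowest level tested, so the fold depended on the log offset; with an offset of 32 their absolute log2 differences were 0.58 to 1.67, and BLNK no longer passed (adjusted p = 0.0548). The other probe sets of CEACAM7 and CEACAM5, 1 each, did not pass. Without quercetin day 5 sample 2 the log2 difference of GPC5 was -1.61, against -3.19 with all arrays. Leaving out 1 array ended the call of 8 of the 20 genes. Without quercetin day 5 sample 2 the adjusted p was 0.0734 for QSOX1, 0.161 for CCDC134, 0.14 for IFITM3, 0.175 for TRABD and 0.058 for GPC5. Without control day 5 sample 1 it was 0.176 for TRABD, 0.0698 for GPR143, 0.0948 for MGAM, 0.129 for GPC5 and 0.102 for XPNPEP2. Without quercetin sample 1 it was 0.0595 for CCDC134, 0.0847 for IFITM3 and 0.224 for TRABD, and without control sample 2 it was 0.0641, 0.173 and 0.0876 for the same genes. The count of probe sets was 1189 and 1040 without quercetin day 5 sample 1 or 2, 1116 and 1191 without control day 5 sample 1 or 2, 1022 without a trend in the variance prior and 737 with a change of at least 2-fold. In that fit without a trend IFITM3, TRABD, MGAM, GPC5 and XPNPEP2 did not pass, with adjusted p from 0.0658 to 0.141, and with only the 4 day 5 arrays CCDC134 and BLNK did not, at 0.0505 and 0.12. With no filter on low values TRABD did not, at 0.0549.

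**Figure D1:**
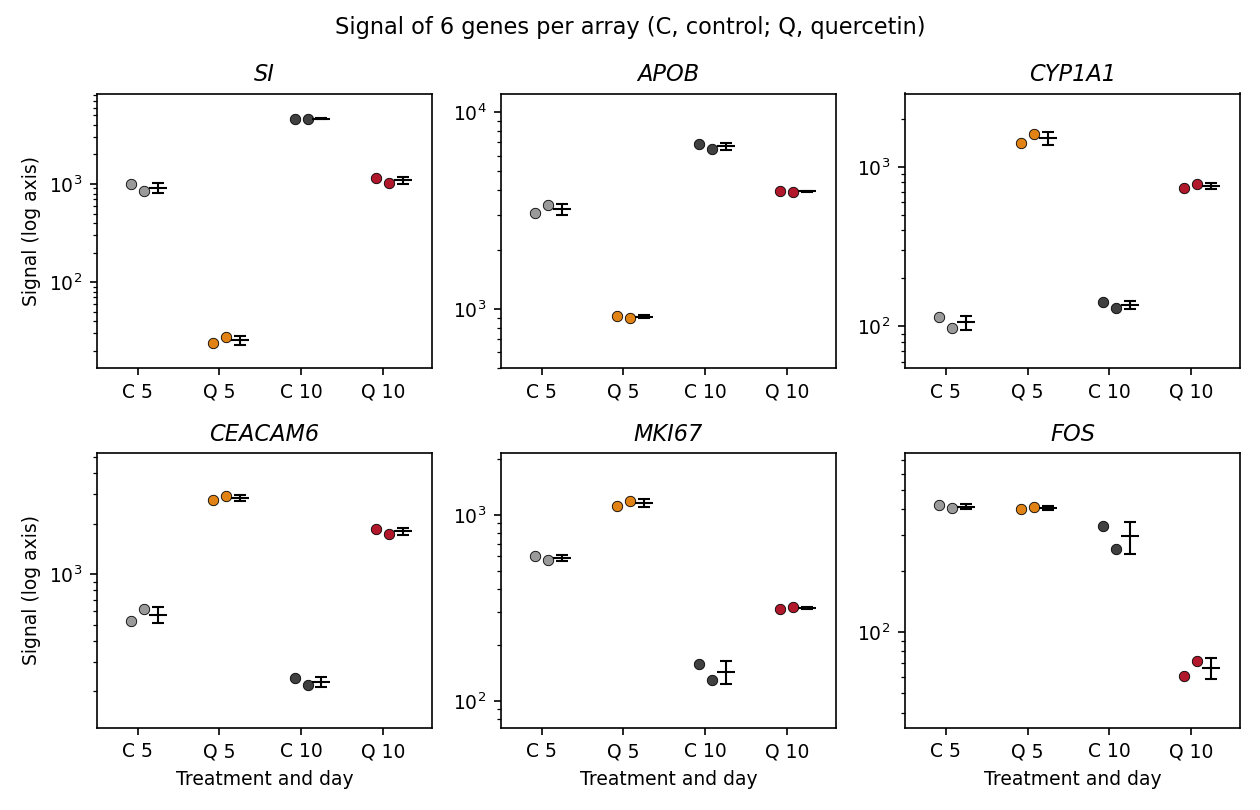
Signal per array (log axis) of SI, APOB, CYP1A1, CEACAM6, MKI67 and FOS in control (C) and quercetin-treated (Q) cells on days 5 and 10; points are the 2 arrays of a group, and the bars beside them are the mean and SD. SI in quercetin-treated cells stayed below control on both days, at 25.8 against 921 on day 5 and at 1088 against 4603 on day 10.

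On day 10, most members of the mitosis list and some of DNA replication were higher in quercetin-treated than in control cells, and some enterocyte and lipid transport genes were lower. TPX2 (a spindle assembly factor) rose 2.31-fold, from a signal of 318 ± 32.4 to 735 ± 36.8 (SD, n = 2), a log2 difference of 1.21 ± 0.107 with an adjusted p of 3.91e-05. CEACAM6 rose 7.84-fold from 229 ± 15.2 to 1802 ± 95.1, a log2 difference of 2.97 ± 0.111 with an adjusted p of 4.51e-08. SI fell 4.23-fold from 4603 ± 53.5 to 1088 ± 85, a log2 difference of -2.08 ± 0.128 with an adjusted p of 2.36e-06. FOS (209189_at), an immediate early transcription factor, fell 4.38-fold from 295 ± 53.8 to 66.2 ± 7.91. Its list, MAPK feedback and immediate early genes, went the other way on balance: of 24 members, 10 rose, 3 fell and 11 did not pass, or 10 and 4 adjusted over the list alone (mean 0.46, list adjusted p = 0.00251, but adjusted p = 0.0946 with an estimated correlation). With limma, 1368 of 14934 probe sets differed, 804 higher and 564 lower, which represented 903 of 8582 genes, 505 higher and 398 lower.

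Nearly the whole mitosis list was higher on day 10. Of 47 members, 43 rose, none fell and 4 did not pass, or 45 rose adjusted over the list alone (mean 0.95, list adjusted p = 3.17e-38, but adjusted p = 0.072 with an estimated correlation). The kinase AURKA rose by 1.11, cyclin B, CCNB1, by 0.97 and the ubiquitin-conjugating enzyme UBE2C by 0.92 on the log2 scale. Of 37 genes of DNA replication and the G1/S transition, 10 rose, none fell and 27 did not pass, or 22 rose adjusted over the list alone (mean 0.56, list adjusted p = 1.20e-09, but adjusted p = 0.072 with an estimated correlation), with the ribonucleotide reductase subunit RRM2 at 0.80 and the clamp loader subunit RFC4 at 0.73. Without a trend in the variance prior neither RRM2 nor RFC4 passed.

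Some genes of the unfolded protein and amino acid response and of cell junctions also rose on day 10. Of 42 genes of the first group, 12 rose, 1 fell and 29 did not pass, or 18 and 1 adjusted over the list alone (mean 0.51, list adjusted p = 5.88e-09, but adjusted p = 0.072 with an estimated correlation). The mitochondrial folate enzyme MTHFD2 rose 2.42-fold from 604 ± 95.5 to 1457 ± 55.7, and the stress-induced transcription factors ATF3 and DDIT3 rose by 1.82 and 1.59 on the log2 scale. Of 22 tight and adherens junction genes, 5 rose, none fell and 17 did not pass, or 10 rose adjusted over the list alone (mean 0.34, list adjusted p = 6.15e-04, but adjusted p = 0.164 with an estimated correlation), with the desmosomal cadherin DSG2 at 0.77. Of 14 aryl hydrocarbon receptor targets, 6 rose, 1 fell and 7 did not pass, the same counts adjusted over the list alone (mean 0.46, list adjusted p = 3.36e-04, but adjusted p = 0.123 with an estimated correlation). CYP1A1 rose 5.57-fold from 136 ± 7.33 to 762.5 ± 30.8, and NQO1 rose by 0.87 on the log2 scale. Of 30 NRF2 targets, 5 rose, 2 fell and 23 did not pass, or 7 and 3 adjusted over the list alone, and the list did not pass (mean 0.06, list adjusted p = 0.351). AKR1C3, an aldo-keto reductase, fell by 0.74 on the log2 scale.

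Some genes of oxidative phosphorylation, lipid transport and drug metabolism fell on day 10. Of 39 genes of oxidative phosphorylation, 9 fell, none rose and 30 did not pass, or 21 fell adjusted over the list alone (mean -0.24, list adjusted p = 1.09e-09, but adjusted p = 0.164 with an estimated correlation), with the complex I subunit NDUFA1 at -0.59 and the cytochrome oxidase subunit COX5A at -0.44, neither of which passed without a trend in the variance prior. Of 19 genes of lipoproteins and lipid transport, 6 fell, none rose and 13 did not pass, or 10 and 1 adjusted over the list alone (mean -0.37, list adjusted p = 2.25e-06, but adjusted p = 0.072 with an estimated correlation), with APOH at -1.55, APOM at -1.01 and APOB at -0.76. Of 37 genes of phase I and II metabolism and drug transport, 11 fell, 2 rose and 24 did not pass, or 13 and 3 adjusted over the list alone (mean -0.32, list adjusted p = 1.79e-04, but adjusted p = 0.123 with an estimated correlation), with the sulfotransferase SULT2A1 at -1.50 and EPHX2 at -0.90. Of 33 brush border and enterocyte markers, 7 fell, 6 rose and 20 did not pass, or 12 and 6 adjusted over the list alone, and the list did not pass (mean -0.15, list adjusted p = 0.102). SI and the carbonic anhydrase CA2 fell by 2.08 and 2.06, while CEACAM6 and CEACAM5 rose by 2.97 and 3.24 on the log2 scale. The other members that rose were KRT20, CEACAM1, MUC13 and GPA33, by 2.479, 1.195, 0.898 and 0.858. The other cell types listed did not pass by camera on day 10, with a list adjusted p of 0.742 for goblet, Paneth, enteroendocrine and stem-like cells and of 0.116 for blood, stroma and endothelium. By fry the blood, stroma and endothelium list passed (mean 0.34, adjusted p = 0.041).

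Among genes that passed on day 10, the 10 largest rises were in the lectin LGALS1, AKAP12, CEACAM7, the phosphodiesterase PDE10A, PTGS2, CEACAM5, MMP7, DBF4B, CEACAM6 and AKIRIN2, with log2 differences from 4.51 down to 2.88. The 10 largest falls were in F13B, RHEX, TAB1, FOS, PRKACA, SI, CA2, the protease inhibitor PI3, SLC2A2 and the collagen gene COL2A1, from -2.79 to -1.84. In 9 of these 20 genes a compared group had a mean signal below 10.5; with an offset of 32 their absolute log2 differences were 0.59 to 1.78, and DBF4B no longer passed (adjusted p = 0.0687). The other probe sets of CEACAM7, CEACAM5, PDE10A and RHEX, 1 each, did not pass. Without quercetin day 10 sample 2 the log2 difference of TAB1 was -1.27, against -2.22 with all arrays. Leaving out 1 array ended the call of 8 of the 20 genes. Without quercetin day 10 sample 1 or 2 the adjusted p was 0.0911 or 0.0761 for MMP7, 0.0954 or 0.099 for DBF4B, 0.0854 or 0.105 for AKIRIN2, 0.142 or 0.139 for F13B, 0.0684 or 0.0533 for RHEX and 0.132 or 0.19 for SLC2A2. Without control sample 1 or 2 it was 0.0932 or 0.159 for F13B and 0.147 or 0.102 for SLC2A2. Without control sample 1 it was 0.0945 for RHEX and 0.0748 for PRKACA, and without quercetin sample 1 it was 0.0708 for PRKACA. TAB1 passed in 1 of the 8 fits that left out an array, that without quercetin day 10 sample 1, and had adjusted p of up to 0.248 in the others. The count of probe sets was 604 and 689 without quercetin day 10 sample 1 or 2, 349 without a trend in the variance prior, 822 with only the 4 day 10 arrays, of which 406 were higher and 416 lower, and 409 with a change of at least 2-fold. With each array centred on its median it was 1029, 528 higher and 501 lower. In that fit without a trend PDE10A, MMP7, F13B, RHEX, TAB1, PRKACA and SLC2A2 did not pass, with adjusted p from 0.0561 to 0.143, and with only the 4 arrays PTGS2, MMP7, DBF4B, AKIRIN2 and TAB1 did not, from 0.0512 to 0.221. With no filter on low values F13B, TAB1 and SLC2A2 did not, at 0.0596, 0.0899 and 0.0722.

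**Figure D2:**
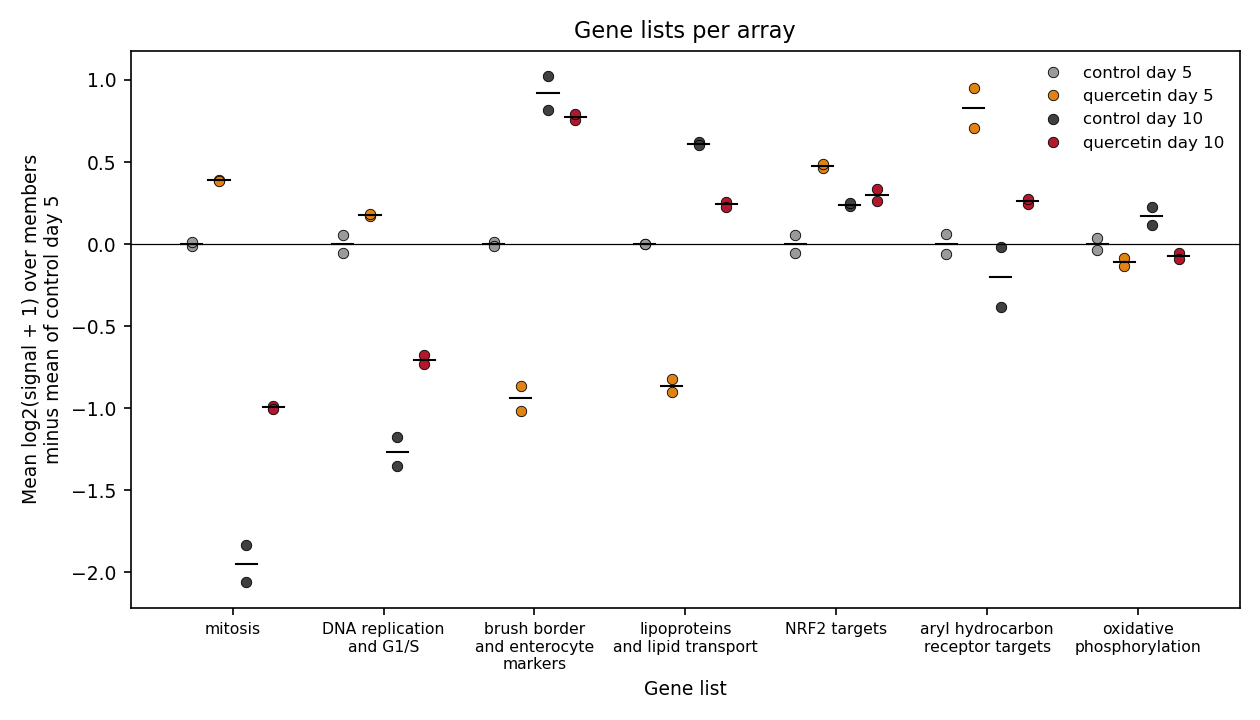
Mean log2(signal + 1) over the members of 7 gene lists on each array, minus the mean of the control day 5 arrays; points are arrays and bars are group means. The mitosis list lay at 0.39 in quercetin-treated cells on day 5, at -1.95 in control cells on day 10 and at -0.996 in quercetin-treated cells on day 10.

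The control cells gave the background against which the quercetin effects stand, the course of an untreated culture after confluency. From day 5 to day 10, the mitosis list fell in control cells, and in the enterocyte, lipid transport and drug metabolism lists more members rose than fell. CCNB1 fell 4.11-fold from a signal of 1578 ± 64.6 to 384 ± 34.2 (SD, n = 2), a log2 difference of -2.04 ± 0.104 with an adjusted p of 3.35e-07. SI rose 5.01-fold from 921 ± 105 to 4603 ± 53.5, a log2 difference of 2.33 ± 0.128 with an adjusted p of 3.64e-07, and APOB rose 2.09-fold from 3214 ± 210 to 6702 ± 278. With limma, 3412 of 14934 probe sets differed, 1716 higher and 1696 lower on day 10, which represented 2205 of 8582 genes, 1148 higher and 1057 lower.

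All 47 mitosis genes fell in control cells, also adjusted over the list alone (mean -1.95, list adjusted p = 1.62e-49, and adjusted p = 0.0459 with an estimated correlation). DLGAP5 and PTTG1, both of the mitotic spindle and chromosome separation, fell by 2.47 and 2.04 on the log2 scale. Of 37 genes of DNA replication and the G1/S transition, 28 fell, none rose and 9 did not pass, or 31 fell adjusted over the list alone (mean -1.27, list adjusted p = 1.48e-19, and adjusted p = 0.0459 with an estimated correlation), with RFC4 at -1.90 and RRM2 at -1.63. Of 21 Wnt and beta-catenin targets, 7 fell, 1 rose and 13 did not pass, the same counts adjusted over the list alone (mean -0.58, list adjusted p = 1.83e-03, but adjusted p = 0.0784 with an estimated correlation), with the survivin gene BIRC5 at -2.21, which is also on the mitosis list, and the hyaluronan receptor CD44 at -2.30. Of 42 genes of the unfolded protein and amino acid response, 17 fell, 3 rose and 22 did not pass, or 19 and 4 adjusted over the list alone (mean -0.35, list adjusted p = 2.13e-03, but adjusted p = 0.203 with an estimated correlation), with MTHFD2 at -1.70 and the asparagine synthetase ASNS at -1.38.

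Of 33 brush border and enterocyte markers, 18 rose, 1 fell and 14 did not pass in control cells, or 19 and 1 adjusted over the list alone (mean 0.92, list adjusted p = 4.85e-08, but adjusted p = 0.079 with an estimated correlation). SLC26A3 and CDHR5, a brush border protocadherin, rose by 2.26 and 3.44 on the log2 scale, and the member that fell was CEACAM6, at -1.32. Of 19 genes of lipoproteins and lipid transport, 13 rose, 1 fell and 5 did not pass, or 14 and 2 adjusted over the list alone (mean 0.61, list adjusted p = 1.66e-06, and adjusted p = 0.0489 with an estimated correlation), with APOA4 at 2.01 and APOM at 1.40. Of 37 genes of phase I and II metabolism and drug transport, 22 rose, 2 fell and 13 did not pass, or 22 and 3 adjusted over the list alone (mean 0.73, list adjusted p = 8.99e-07, but adjusted p = 0.0784 with an estimated correlation), with the carboxylesterase CES1 at 0.98 and the transporter SLC22A4 at 2.01. Of 19 metallothioneins and genes of metal homeostasis, 9 rose, none fell and 10 did not pass, or 10 rose adjusted over the list alone (mean 0.72, list adjusted p = 2.22e-04, but adjusted p = 0.0679 with an estimated correlation), with the iron carrier TF at 1.63 and the metallothionein MT1X at 1.97. Of 35 inflammatory and acute phase genes, 13 rose, 2 fell and 20 did not pass, or 13 and 3 adjusted over the list alone (mean 0.37, list adjusted p = 5.98e-04, but adjusted p = 0.0679 with an estimated correlation), with FGB at 1.49 and the retinol carrier RBP4 at 1.63. Metallothionein and UGT2B probe sets can bind the transcripts of near-identical relatives, which was not tested.

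Among genes that passed in control cells, the 10 largest rises were in UGT2B17, a glucuronosyltransferase, the glucose-6-phosphatase G6PC1, the receptor CUBN, TNFSF10, CYP2B7P, CDHR5, PI3, SLC2A2, F13B and the bile acid transporter SLC10A2, with log2 differences from 5.28 down to 3.12. The 10 largest falls were in PPP2R3B, DBF4B, PHLDA3, CENPE, NRP1, ORC1, APOBEC3F, PTGS2, LGALS1 and CDC45, from -3.39 to -2.80. In 10 of these 20 genes a compared group had a mean signal below 10.5; with an offset of 32 their absolute log2 differences were 0.65 to 2.48. Leaving out 1 array ended the call of 6 of the 20 genes. Without control day 5 sample 2 the adjusted p was 0.053 for DBF4B, 0.119 for PHLDA3, 0.161 for NRP1, 0.0565 for ORC1 and 0.186 for CDC45, and without control day 5 sample 1 it was 0.0734 for APOBEC3F, 0.0738 for NRP1 and 0.0995 for CDC45. NRP1 also missed the threshold without quercetin day 5 sample 1 (0.0501) or 2 (0.0506) and without control day 10 sample 1 (0.0516) or 2 (0.0596). CDC45 also missed it without control day 10 sample 1, where its log2 difference was -0.81 (adjusted p = 0.149), and without any 1 of the 4 quercetin arrays, at 0.0536 to 0.0565. The count of probe sets was 2230 and 2022 without control day 5 sample 1 or 2, 1915 without a trend in the variance prior and 1205 with a change of at least 2-fold. In that fit without a trend NRP1, ORC1 and CDC45 did not pass, at 0.0688 to 0.174, and with only the 4 control arrays DBF4B, PHLDA3, NRP1, PTGS2, LGALS1 and CDC45 did not, at 0.0563 to 0.0831. With no filter on low values CDC45 did not, at 0.0619. With each array centred on its median, which moved the median log2 difference of all probe sets from 0.029 to -0.075, the calls split into 1171 higher and 1959 lower.

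Genes that changed from day 5 to day 10 in control cells tended to differ the opposite way in quercetin-treated cells on day 10. Of the 505 genes higher with quercetin on day 10, 336 fell in control cells over time, against 62.2 for independent calls, and 2 rose. Of the 398 genes lower with quercetin, 277 rose in control cells, against 53.2, and 2 fell. Across 8582 genes, which are not independent replicates, the quercetin effect on day 10 and the control course correlated with r = -0.63. Both share the control day 10 arrays, which also raises the number of opposite calls and alone gave r = -0.50 in 100 simulations of unchanged groups. From disjoint arrays, r was -0.36 with sample 1 for the first comparison and sample 2 for the second, and -0.25 the other way round. The covariance, -0.237, lay below the simulated value of -0.07. The quercetin effect on day 5 and the control course also ran opposite, with r = -0.27 and -0.22 from disjoint arrays.

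**Figure D3:**
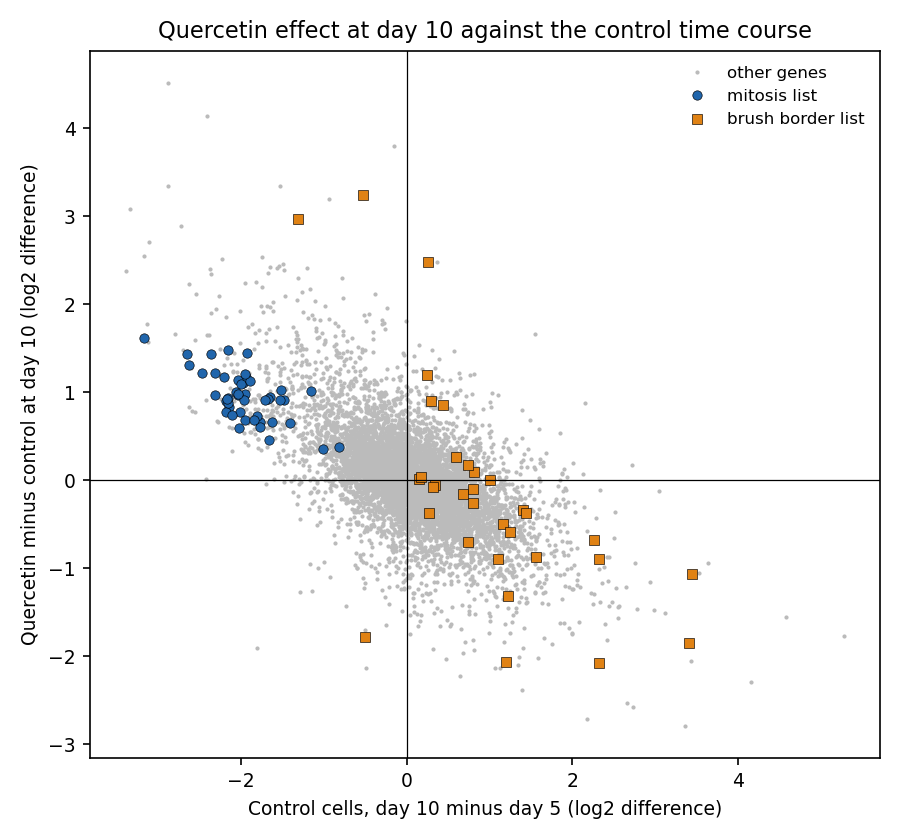
Log2 difference between quercetin-treated and control cells on day 10 against the log2 difference from day 5 to day 10 in control cells; each point is 1 of 8582 genes, with mitosis genes as circles and brush border and enterocyte markers as squares. All 47 mitosis genes lay in the upper left quadrant, and 20 of 33 brush border markers lay in the lower right, while both axes share the control day 10 arrays.

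The quercetin effects of both days shared many genes. Of the genes called, 195 were higher and 210 lower on both days, against 31.3 and 39.2 for independent calls, whereas 7 were higher on day 5 and lower on day 10 and 17 the reverse, against 24.7 and 49.8. Across 8582 genes the effects correlated with r = 0.40, and with r = 0.30 and 0.26 from disjoint arrays, beside 0.002 simulated for unchanged groups. Averaged over both days, 2897 of 14934 probe sets differed with quercetin, 1413 higher and 1484 lower, by limma. The largest average rises were in AKAP12, CEACAM7, MMP7, CEACAM5 and LGALS1 (log2 differences 3.99 to 3.18) and the largest falls in SI, SLC2A2, GPC5, RHEX and F13B (-3.59 to -2.45). In 8 of these 10 genes a compared group had a mean signal below 10.5, and with an offset of 32 their absolute differences were 1.04 to 2.25. The other probe sets of CEACAM5 and RHEX, 1 each, did not pass. The count was 1656 without a trend in the variance prior, where GPC5 did not pass (adjusted p = 0.056), and 514 with a change of at least 2-fold.

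Quercetin-treated cells also changed between day 5 and day 10. Brush border and enterocyte markers rose in 24 of 33 cases, 1 fell and 8 did not pass, or 24 and 2 adjusted over the list alone (mean 1.72, list adjusted p = 3.53e-13, and adjusted p = 0.0481 with an estimated correlation), and 45 of 47 mitosis genes fell, none rose and 2 did not pass, or 46 fell adjusted over the list alone (mean -1.38, list adjusted p = 4.88e-35, and adjusted p = 0.0481 with an estimated correlation). The largest rises were in SLC2A2, BLNK, SI, SLC26A3 and CEL (log2 differences 5.53 to 4.42), and the largest falls in FKBP5, NPTX1, L1CAM, CST1 and MICB (-3.66 to -2.81). With limma, 3873 of 14934 probe sets differed, 2179 higher and 1694 lower. In 5 of these 10 genes a compared group had a mean signal below 10.5, with absolute differences of 0.92 to 2.23 at an offset of 32. The count was 2462 and 2545 without quercetin day 5 sample 1 or 2, 2543 without quercetin day 10 sample 2 and 1504 with a change of at least 2-fold, and CST1 did not pass without a trend in the variance prior (adjusted p = 0.0558). With each array centred on its median, which moved the median log2 difference of all probe sets from 0.069 to -0.11, the calls split into 1371 higher and 2492 lower.

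The quercetin effect itself differed between the days for some genes. SI and GUCY2C, the guanylin receptor, lay less far below control on day 10 than on day 5, with differences between the effects of 3.02 ± 0.181 and 2.35 ± 0.214 on the log2 scale (SE). FOS, with 406.6 ± 9.45 against 413 ± 11.3 on day 5 and 66.2 ± 7.91 against 295 ± 53.8 on day 10, had a difference of -2.11 ± 0.239, and the metallothionein MT1X one of -2.23 ± 0.321. By this test of the difference, 415 of 14934 probe sets passed with limma, 309 in the higher direction and 106 in the lower. Without a trend in the variance prior limma called 0, with a smallest adjusted p of 0.0558, and 2142 probe sets at an unadjusted p under 0.05.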

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

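In this part, the tests of shared control arrays, of scaling, of the sample number and of genes apart from both controls, with the alternatives to it, were chosen only after the results they concern were seen.

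The results below stand out because the quercetin effect differed between day 5 and day 10 in a test of that difference itself, which passed for 415 probe sets at an adjusted p under 0.05 with limma. Values are the day 10 effect minus the day 5 effect in log2 units, with SE. Without a trend in the variance prior limma called 0 of them (2142 at an unadjusted p under 0.05, smallest adjusted p 0.0558), and leaving out 1 array gave 212, 227, 186, 224, 162 and 253 without quercetin day 5 sample 1 or 2, control day 5 sample 1 or 2, and quercetin day 10 sample 1 or 2. SI differed by 3.02 ± 0.181 (adjusted p = 1.26e-05), GUCY2C by 2.35 ± 0.214 (0.000177), GNRH2 by 2.92 ± 0.301 (0.000347), AKR1D1 by 1.96 ± 0.345 (0.00964) and CEACAM6 by 0.66 ± 0.157 (0.047). FOS differed by -2.11 ± 0.239 (0.000659), MT1HL1 by -2.76 ± 0.389 (0.00266), MT1X by -2.23 ± 0.321 (0.00292), CYP1A1 by -1.34 ± 0.198 (0.00342), PI3 by -1.28 ± 0.247 (0.0163) and COL2A1 by -0.91 ± 0.179 (0.0186). REEP2 differed by 3.50 ± 0.787 (0.0344; its mean signal under quercetin on day 5 was 5.98, below the 10.5 that is the lowest level tested, and with an offset of 32 the difference was 1.32, adjusted p = 0.0177), AOX1 by 2.85 ± 0.641 (0.0344), B3GAT3 by -2.66 ± 0.539 (0.0207) and VARS1 by -1.87 ± 0.367 (0.0182). GNRH2 lay below control on day 5 (-1.631) and above it on day 10 (1.284). The mean signals of REEP2, AOX1, MT1HL1, MT1X, B3GAT3 and VARS1 also lay on opposite sides of control on day 5 and day 10. AKR1D1 had a mean signal of 6.865 under quercetin on day 5, and with an offset of 32 its difference was 0.28 ± 0.245 (adjusted p = 0.607). CEACAM6 did not pass with an offset of 32 (0.065) or median centring (0.149). SI passed with that offset, at a smaller difference of 1.99 ± 0.163 (3.12e-05). Leaving out 1 array ended the call of REEP2 in 7 of 8 fits (adjusted p up to 0.163), of CEACAM6 in 7 (up to 0.191), of PI3 in 5 (up to 0.0688), of COL2A1 in 4 (up to 0.0939), of AKR1D1 in 2 (0.0507 and 0.0705, without control day 5 sample 2 or quercetin day 10 sample 1), of AOX1 in 5 (up to 0.128), of B3GAT3 in 5 (up to 0.0894) and of VARS1 in 4 (up to 0.0845). With no filter on low values the adjusted p was 0.0691 for REEP2, 0.0683 for AOX1 and 0.054 for both B3GAT3 and CEACAM6, and over means of all probe sets of a gene 0.335 for AOX1, 0.138 for B3GAT3 and 0.547 for CEACAM6. Over such means the difference was 1.311 for AOX1, -1.835 for B3GAT3 and -3.177 for VARS1. With an offset of 32 it was 1.635 for AOX1 and -1.363 for B3GAT3, and both passed. The other probe sets of AOX1, B3GAT3, VARS1, CEACAM6, PI3 and COL2A1, 1 each, did not pass.

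By the preset correlation, 12 of 29 lists differed between the days, and none did with an estimated correlation, where adjusted p ranged from 0.0898 to 0.451. The mean difference was 0.80 for brush border and enterocyte markers (list adjusted p = 3.47e-09, estimated 0.149), 0.50 for lipoproteins and lipid transport (8.81e-06, estimated 0.0898), 0.44 for phase I and II metabolism and drug transport (3.77e-03, estimated 0.228), 0.57 for mitosis (3.80e-12, estimated 0.204) and 0.38 for DNA replication and G1/S (6.45e-03, estimated 0.243). It was 0.31 for inflammatory and acute phase genes (4.30e-03, estimated 0.149) and 0.39 for goblet, Paneth, enteroendocrine and stem-like markers (0.0325, estimated 0.228). It was -0.42 for NRF2 targets (1.96e-07, estimated 0.0898), -0.38 for heat shock proteins (3.67e-05, estimated 0.204), -0.37 for aryl hydrocarbon receptor targets (0.0268, estimated 0.269), -0.24 for cholesterol synthesis (4.30e-03, estimated 0.207) and -0.13 for oxidative phosphorylation (1.53e-03, estimated 0.451).

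The day 10 effect minus the day 5 effect was positive in 27 of 33 members of the brush border list, with a mean of 0.80. If saturated signals in control cells on day 10 were the cause, the difference would vanish among members below saturation. Over the 31 members with no array above the 99th percentile of signals (4716) it was 0.82 ± 0.178 (SE over members). The difference thus did not rest on the 2 members left out. That cut is not a known saturation level, since signals reached 11103, so it cannot decide whether saturation played a part. An SE over members, here and below, treats genes as independent and does not measure the spread between arrays. Under quantile normalization the mean was 0.759, and under median centring 0.721. These scalings moved the median log2 difference of the probe sets tested only from 0.055 to 0.027 and -0.02, so they could not have removed the difference. It did not depend on the choice among these scalings, but they were too alike to decide whether scaling played a part. Low signals near the log offset are argued against as the whole cause by a mean of 0.449 ± 0.125 (SE over members) with an offset of 32. That mean was below the 0.80 of the main fit, so part of the difference depended on the offset. Saturation, scaling, and low signals as part of the cause, thus stay open. Also open, and untested by this design, is a biological hypothesis, an enterocyte program that starts later under quercetin. The same holds for an effect of the end of exposure after 9 days.

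Across genes, the difference between quercetin-treated and control cells on day 10 ran opposite to the control time course. The correlation was -0.627, beside -0.50 simulated for unchanged groups that share arrays. Between the days, quercetin-treated cells changed the same way as control cells in the mitosis list (means -1.38 and -1.95) and the brush border list (1.72 and 0.92). The sharing of control arrays is argued against as the whole cause by a mean r of -0.301 across genes from disjoint arrays. If both control day 10 arrays came from 1 culture, disjoint arrays would still share it, so a shared culture is not excluded. Under quantile normalization the mean difference of the mitosis list on day 10 was 0.969 ± 0.041 (SE over members). That scaling moved the median log2 difference of the probe sets tested only from 0.013 to 0.003, so the list mean could hardly have fallen. The value shows that the list's difference did not depend on the choice between these scalings. It cannot decide whether scaling shaped the pattern across genes. A delay of the control course as the whole quercetin effect is argued against, but weakly, by 40 of 8582 genes. Under quercetin on day 10 these differed from both control groups in the same direction by the larger of 2 p-values, adjusted over all genes. Their control levels could still have passed through a peak or a trough outside the days sampled. The count fell to 4 without a trend in the variance prior. It also fell where any quercetin day 10 or control day 5 array was left out. In the fit without a trend, and in those without a quercetin day 10 array, it missed the bound for this test. That bound was itself set after the result was seen. Of the 903 genes called on day 10, 17.3% (156) also differed from control on day 5 in that direction, between the bounds set in advance, so a delay of part of the genes stays open beside an effect apart from the course, as hypotheses.

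The 18S ribosomal RNA 5' control signal was higher on sample 1 than on sample 2 in each of the 4 groups, with ratios of 1.84 for quercetin day 5, 1.97 for control day 5, 7.2 for quercetin day 10 and 27.2 for control day 10. If the sample number marked a batch that moves many probe sets, deviations of same-numbered arrays would correlate across groups, but the largest of 6 correlations was 0.047. No biological explanation was tested for this pattern.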

How the results depend on the processing

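None of these alternatives was chosen after the results were seen, and the cause of a change was not tested except where the setting itself removes arrays or probe sets. The counts of probe sets below are given for quercetin on day 5, on day 10, the control course, the course under quercetin, the difference between the quercetin effects, and their average, which stood at 2170, 1368, 3412, 3873, 415 and 2897. With a change of at least 2-fold they were 737, 409, 1205, 1504, 250 and 514. Without a trend in the variance prior they were 1022, 349, 1915, 2709, 0 and 1656. Over means of all probe sets of a gene, a smaller number of tests, 1320 were called on day 5, 2124 in the control course, 2463 in the course under quercetin, 264 for the difference and 1780 for the average. With only the 4 arrays compared, the day 10 count was 822, 406 higher and 416 lower against 804 and 564. Median centring gave 276 for the difference, 173 higher and 103 lower against 309 and 106, and split day 10 into 528 and 501, the control course into 1171 and 1959 against 1716 and 1696, and the course under quercetin into 1371 and 2492 against 2179 and 1694. With the sample number as a block, which the check of pairs at -0.031 to 0.047 did not call for, the counts were 2095, 1321, 3367, 3786, 401 and 2789, and TRABD on day 5 missed the threshold (adjusted p = 0.0522). Leaving out 1 array gave ranges of 1040 to 2586, 604 to 1191, 2022 to 3222, 2462 to 4314, 162 to 577 and 1983 to 2940. The 20, 14 and 12 lists called in the 3 main comparisons became 2, 0 and 3 with an estimated correlation, and 14 to 19, 12 to 15 and 10 to 13 without 1 array. The brush border list on day 10 passed without quercetin day 5 sample 1 (adjusted p = 0.0493), and NRF2 targets on day 10 passed by fry (0.0387). The correlation between the quercetin effects was 0.399, 0.184 with no filter, 0.507 without the lower 50% of probe sets, and 0.334 to 0.39 without 1 array. That of the day 10 effect with the control course was -0.627, -0.566 with no filter, and -0.713 to -0.545 without 1 array. The control course and the average, split nearly evenly, changed which direction held more, for example 1572 and 1767 in the course under quantile normalization, and 1521 and 1419 against 1413 and 1484 in the average without control day 10 sample 1. No named gene result changed its direction under the alternatives run for it. Nor did any of 29 list results under quantile normalization, means over a gene, no filter, fry, an estimated correlation or without 1 array. For lists, a change was counted only where the list passed in the main fit or in the alternative. Neither correlation changed its direction under quantile normalization, no filter, without the lower 50% or without 1 array. Of 195 named gene results, 157 passed in each of the 8 fits without 1 array. Signals near background limit the folds of named genes, which shrink there with a larger offset.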

Other observations

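In this part, the test by the larger of 2 p-values was chosen only after the result it concerns was seen, and the genes named first were chosen after their values were seen.

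Some genes under quercetin on day 10 lay beyond both control groups, that is, they differed from control on day 10 and on day 5 in the same direction. Of 903 genes called on day 10, 156 did so, 101 higher and 55 lower, and 77 of them were also called the same way on day 5. Both comparisons use the same quercetin day 10 arrays, and the number that unchanged genes would give was not computed. By the larger of the 2 p-values, adjusted over all 8582 genes, 40 differed from both, or 9 and 7 without quercetin day 10 sample 1 or 2, 24 and 13 without control day 5 sample 1 or 2, and 4 without a trend in the variance prior. The brush border list members that rose on day 10 were all among the 156 genes. One of them, KRT20, is a keratin of mature intestinal epithelium. KRT20 was higher than control day 10 by 2.48 ± 0.301 and than control day 5 by 2.73 ± 0.301 on the log2 scale (SE). KLF4, an epithelial transcription factor, was higher by 1.44 ± 0.17 and 1.40 ± 0.17. S100P, a calcium-binding protein, was higher by 2.18 ± 0.135 and 1.01 ± 0.135, and EMP1, an epithelial membrane protein, by 2.12 ± 0.184 and 1.73 ± 0.184. PCK1, the rate-limiting enzyme of gluconeogenesis, was higher by 2.41 ± 0.204 and 1.21 ± 0.204, whereas on day 5 its log2 difference was 0.07 with an adjusted p of 0.879. CFTR, the epithelial chloride channel, was lower than both, at -1.31 ± 0.18 and -1.12 ± 0.18.

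Further lists passed with quercetin. Of 36 genes of extracellular matrix and the TGF-beta response, 10 rose and 5 fell on day 5, or 12 and 5 adjusted over the list alone (mean 0.30, list adjusted p = 0.0164, but adjusted p = 0.148 with an estimated correlation), and 9 rose and 3 fell on day 10, or 11 and 3 adjusted over the list alone (mean 0.31, list adjusted p = 0.0232, but adjusted p = 0.164 with an estimated correlation). Of 21 glycolysis genes, 4 rose and none fell on day 5, also 4 adjusted over the list alone (mean 0.29, list adjusted p = 0.0056, but adjusted p = 0.18 with an estimated correlation), and 4 rose and 1 fell on day 10, or 5 and 1 adjusted over the list alone (mean 0.22, list adjusted p = 0.0134, but adjusted p = 0.227 with an estimated correlation). Of 21 Wnt and beta-catenin targets, 5 rose and none fell on day 10, or 7 and 1 adjusted over the list alone (mean 0.57, list adjusted p = 0.0019, but adjusted p = 0.0946 with an estimated correlation), beside a mean of -0.58 in the control course. RNA quality and housekeeping controls did not pass by camera, with list adjusted p of 0.348 on day 5, 0.971 on day 10 and 0.844 in the control course, and neither did markers of blood, stroma and endothelium, at 0.693, 0.116 and 0.0957. By fry the latter passed on day 10 (adjusted p = 0.041) and in the control course (0.025).

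With day as a second term, the treatment split called 1971 probe sets. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many, the real one and the split by day, which gave 2710, the highest other. By that share chance is not excluded. Since the split by day gave more, the share could not fall under 0.05, so it cannot decide the question. The treatment split did give more than every split but that by day, as the bound set in advance asked, but that bound leaves out a split which the share counts. The split by day follows a factor of the design, was fitted without a second term, and points to a structure of the samples, while the others gave 0. Fits of those others left part or all of the treatment effect in the residual spread.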
